A study of Arabidopsis thaliana with 16 samples.

How the data were processed

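RNA was sequenced from inflorescences with juvenile leaves of Arabidopsis, Col-0 wild type and the zed1-D mutant. Per the labels' protocols, plants grew under 16 h of light at 18 °C until the primary stem had bolted, then moved to 28 °C, and RNA was caught on (dT) beads. Samples were taken 0, 3, 12 and 48 h after the move, and groups and replicate numbers came from the titles. The labels give no sampling clock time and do not say whether replicates were separate plants, pools or repeated libraries.

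Per the file headers, the deposited values are counts of uniquely mapped reads per gene in each library, and only genes with at least 1 read are listed. A gene missing from a library was taken as 0. The counts summed to the total in each file's header. The deposited RPKM values, made by the authors from those counts, were only checked: recomputing them from each file's counts, lengths and total gave a largest relative difference of 0. Gene length differed between libraries for 317 genes, which affects RPKM alone. The build was TAIR10 per the submitters' processing notes. The aligner, counting tool, annotation release and strand setting are not given in the sources used here. Of 25444 identifiers, 24237 matched a RefSeq locus for their symbol, and 989 carried a transcript suffix. Only names and exonic length and GC content were taken from the reference, no coordinates. Counts of near-identical copies (SAUR20, LHCB1.1, RBCS2B, PDF1.2A, VGD1 and VGDH1, VSP1 and VSP2, COR15A and COR15B) or of genes overlapping on the other strand are uncertain, since unique mapping drops shared reads and the strand setting is unknown.

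Depth was 4.74 M to 11.39 M counted reads per library, and 19056 genes had a read in all 16. The chi-square per degree of freedom between replicates, over genes with at least 20 reads in sum, ran from 15.65 (zed1-D 48 h) to 30.85 (WT 0 h), where counting error alone gives 1. It includes the difference between the replicate sets.

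Counts were fitted with the edgeR quasi-likelihood model (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3; TMM scaling and the default expression filter), with 1 mean per group over all 16 libraries and 8 residual degrees of freedom. The filter kept 19312 genes. The common coefficient of variation was 22.6%. A set of 13 contrasts was tested: zed1-D against WT at each time, each later time against 0 h within a genotype, and the 3 interactions. P-values are two-sided and adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. CPM values are TMM-scaled and shown as mean and SD of 2 libraries. Principal components used log2 CPM with a prior count of 2.

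The replicate numbers pair the libraries. Deviations from the group mean were compared between same-numbered libraries for the 28 pairs of groups, and correlated at 0.53 to 0.71 (median 0.65). The pairing comes from the numbers in the titles and from this check, since the labels do not say what a number shares. The model without the block was set before the data were examined and is the one reported, with blocked results beside it (7 residual degrees of freedom, coefficient of variation 5.7%).

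The 18 gene lists, with 302 genes, were fixed before the data were examined, and 22 of these genes were not tested for lack of reads. Each list was tested with camera, which compares a list's genes with all others, at a preset correlation of 0.01 and again with an estimated one, adjusted over 72 genotype, 108 time and 54 interaction tests. Of 234 tests, 146 passed with the preset and 84 with the estimated correlation. fry, which tests whether a list's genes move on balance one way and compares them with no other gene, was run and is not used for calls. Tapetum, pollen and leaf lists stand for tissues the sampled material can hold, the clock list for time of day and the reference genes for scaling.

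Named genes followed a rule fixed before the data were examined. For each genotype contrast it takes the 5 largest fold changes in each direction among passing genes with a mean log2 CPM of at least 2 and groups that do not overlap, and up to 4 members per list with the smallest p. For time contrasts it takes the 3 largest in each direction and up to 3 list members per list, and for interactions the 5 smallest p in each direction and list members as for time. ZED1, ZAR1, SNC1 and PR1 are allowed in every contrast. Not every gene the rule allows is printed.

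The procedure was tested on simulated data with the same design and depths for zed1-D against WT at 3 h. Of genes simulated to change by a log2 fold of 0.5, 1 and 2, the unblocked model recovered 0%, 22.4% and 69.7% (67, 67 and 66 genes), with 0 false among 61 calls in edgeR. The blocked model recovered 59.7%, 97.0% and 100%, with 11 false of 182 (6.04%). The first pass mark for recovery at a log2 fold of 2 in the unblocked model was not met, and after seeing this it was required of the blocked model alone.

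Alternatives were DESeq2 1.42.0, its size factors in edgeR (RLE), no expression filter, the replicate block, a fit of the compared groups alone, each library left out in turn, and a fold minimum. Thinning all libraries to equal depth was added after seeing the data. Random regroupings were not used since groups hold 2 libraries. Tables were read with Python 3.11.15 and figures drawn with matplotlib 3.10.9.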

Results

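Inflorescences with juvenile leaves were compared between wild-type (WT) Arabidopsis and zed1-D, which carries a dominant allele of the pseudokinase gene ZED1. Plants raised at 18 °C were moved to 28 °C after bolting and sampled after 0, 3, 12 and 48 h. The 8 groups held 2 libraries each. Counted reads were 4.74 M to 5.86 M in replicate 1 (R1) and 10.35 M to 11.39 M in replicate 2 (R2) libraries. Of 25444 genes listed, 19312 passed the expression filter and were tested. Brackets give mean CPM ± SD of 2 libraries in the first group against the second, then log2 fold change ± standard error and FDR, the adjusted p. A gene or list passed at an FDR under 0.05. For lists brackets give passing members where a list passed, the median log2 fold change, the FDR with a preset correlation between genes and, as estimated, the adjusted p with a correlation estimated from the data. For lists passing only with the preset in comparisons with 0 h and interactions the median is left out. Member counts given there without a direction go the way of the list. Where no member passed there, the members at an unadjusted p under 0.05 in edgeR and those called by DESeq2 follow. In comparisons of zed1-D with WT, list alone marks members passing when adjusted over the list alone, given where that differs. Gene p-values measure only the spread between these libraries. List p-values instead compare members with other genes. The labels do not say what the replicates were.

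The first principal component held 35.2% of the variance. It placed all WT libraries between -48.34 and -16.8, the zed1-D libraries at -24.28 and -23.11 at 0 h, 6.46 and 9.5 at 3 h, 62.29 and 68.56 at 12 h, and 70.54 and 71.37 at 48 h. The second component, with 21.9%, split the libraries by replicate number, from 17.27 to 49.02 for replicate 1 and from -44.73 to -12.92 for replicate 2. Results with the replicate number as a block, written as blocked, or blocked estimated for a list with the estimated correlation, are therefore given where they change a call or move a count by over 1.5 times. Counts with the fold minimum required an absolute log2 fold change of 1. Of 289 named gene and comparison pairs 270 passed, and 139 did when each comparison was fitted on its own groups alone. A group left with 1 library was taken to vary like the others. Where leaving out a library ended a named gene's call, the omission with the highest adjusted p is named. Brackets give that p and how many of the 4 omissions, or 8 for an interaction, ended the call. Chloroplast-encoded genes took 0.591% to 2.28% of the counts and were the larger share in the replicate 2 library of every group. Mitochondrion-encoded genes took 0.0194% to 0.0614%.

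**Figure D1:**
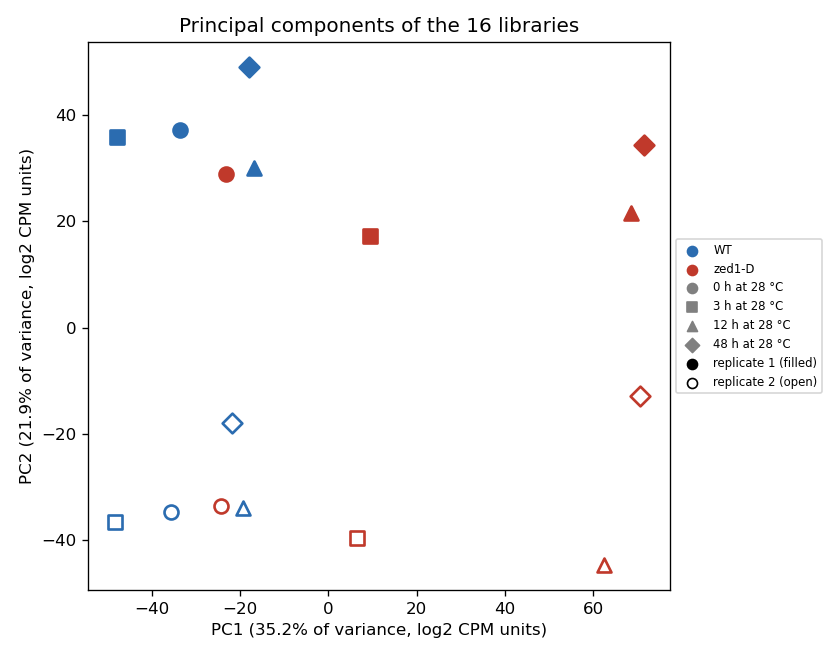
Principal components of the 16 libraries, on axes in log2 CPM units, coloured by genotype with a shape per time. Filled points are replicate 1, all above 0 on the second component, and open points replicate 2, all below.

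ZED1 itself was weakly expressed and did not pass in any genotype comparison. Its level in zed1-D against WT was 9.12 ± 6.69 against 9.39 ± 3.79 CPM at 0 h (0.00 ± 0.70, FDR 1) and 7.55 ± 4.46 against 7.89 ± 5.32 CPM at 3 h (-0.09 ± 0.70, FDR 1). The 12 h (11.3 ± 6.64 against 8.04 ± 2.84 CPM, 0.49 ± 0.69, FDR 0.83, blocked 0.021) and 48 h values (7.44 ± 4.88 against 8.37 ± 2.23 CPM, -0.14 ± 0.7, FDR 0.94) did not pass either. Without a single library the log2 value ran from -1.12 (without zed1-D 0 h replicate 2) to 0.96 (at 3 h, without WT 3 h replicate 2), and no omission gave a call. ZAR1, the immune receptor that works with ZED1, did not pass at 0 h (-0.05 ± 0.18, FDR 1). The 7 measured ZED1-related kinases had no passing member at any time, with medians of -0.18, 0.15, 0.07 and -0.01 and adjusted p = 0.23, 0.74, 0.9 and 0.9. At 48 h their test pointed up although the median was below 0. In edgeR 1 of the 7 had an unadjusted p under 0.05, at 12 h, and DESeq2 called 0. Blocked, 3 were higher at 12 h and 1 at 48 h.

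Before the move to 28 °C a small set of defence genes was already higher in zed1-D. FMO1, which makes the immune signal N-hydroxypipecolic acid, was higher (5.74 ± 1.62 against 1.18 ± 0.0826 CPM, 2.29 ± 0.26, FDR 0.011), as was UGT76B1 (1.96 ± 0.18, FDR 0.0026), a glucosyltransferase acting on the same signal. PAD3 of camalexin synthesis (1.45 ± 0.21, FDR 0.047), the regulator CBP60G (1.2 ± 0.16, FDR 0.037) and PR4 (1.6 ± 0.21, FDR 0.029) were also higher. AT2G30766, a short peptide gene of the iron-deficiency response, was higher (1.95 ± 0.18, FDR 0.0026). HA8, a plasma membrane proton pump, was lower (10.7 ± 2.04 against 56.8 ± 5.97 CPM, -2.43 ± 0.28, FDR 0.012). CYP71A13 of camalexin synthesis (1.99 ± 0.3, FDR 0.057, blocked 6.4e-10), ALD1 (1.29 ± 0.31, FDR 0.43, blocked 0.0011) and PR1 (143 ± 46.1 against 75.4 ± 23.3 CPM, 0.93 ± 0.38, FDR 1, blocked 1e-09) did not pass. Neither did the cold-response gene COR15A (-0.58 ± 0.2, FDR 1, blocked 2.1e-06) or the immune receptor SNC1 (0 ± 0.14, FDR 1).

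Of the fixed lists at 0 h, salicylic-acid defence (2 higher of 22, list alone 6 higher, blocked 9 higher, median 0.33, FDR 5.5e-14, estimated 0.011) and the pattern-triggered and camalexin genes (1 higher of 18, list alone 3 higher, blocked 3 higher, median 0.17, FDR 1.5e-10, estimated 0.00092) shifted up. Cold-response genes shifted down (0 of 7, blocked 5 lower, median -0.39, FDR 2.5e-05, estimated 0.013). So did meristem and floral identity genes (0 of 22, blocked 1 lower, median -0.4, FDR 2e-06, estimated 0.027), tapetum markers (0 of 10, list alone 1 lower, blocked 4 lower, median -0.56, FDR 9.2e-08, estimated 0.0088) and pollen markers (0 of 5, list alone 2 lower, blocked 1 lower, median -0.68, FDR 5e-06, estimated 0.0094). Cell-cycle genes shifted up (0 of 22, blocked 1 higher, median 0.15, FDR 0.00043, estimated 0.015). The jasmonate list (0 of 18, list alone 4 higher and 1 lower, blocked 5 higher and 2 lower, median 0.27, FDR 0.00013, estimated 0.29, blocked estimated 0.045) passed upward only with the preset correlation. Leaf photosynthesis markers (0 of 28, blocked 11 lower, median -0.23, FDR 0.00045, estimated 0.51) and warm-temperature growth genes (0 of 18, median -0.17, FDR 0.027, estimated 0.082, blocked FDR 0.052) passed downward only with it. Where no member passed edgeR gave an unadjusted p under 0.05 for 6 jasmonate, 2 cold-response, 4 floral, 2 tapetum, 2 pollen and 1 cell-cycle genes. DESeq2 called only 1 jasmonate gene there.

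The remaining lists did not pass at 0 h: endoplasmic reticulum (ER) chaperones (0.14, FDR 0.06, blocked 0.0019), heat shock (0.03, FDR 0.064), clock (-0.23, FDR 0.068), immune receptors (-0.02, FDR 0.9), glucosinolate (0.03, FDR 0.9) and reference genes (-0.02, FDR 0.9). For senescence the median was below 0 while the test pointed up (-0.06, FDR 0.9). No member of these lists passed. In edgeR these lists had 2 heat shock, 1 clock, 3 senescence and 1 glucosinolate genes at an unadjusted p under 0.05, and DESeq2 called 0.

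In total 9 genes passed at 0 h, 8 higher and 1 lower in zed1-D. The count was 438 (212 lower) blocked, 0 in the compared groups alone, 34 (5 lower) with DESeq2 and 6 (1 lower) thinned, where edgeR on the compared groups gave 239 genes at an unadjusted p under 0.05. It was 0 and 0 without WT 0 h R1 or R2, 3 and 2 without zed1-D 0 h R1 or R2 (unadjusted 526 and 617 genes without WT replicates 1 and 2). AT2G30766 (0.094, 2), FMO1 (0.22, 3), PAD3 (0.49, 4), PR4 (0.48, 4) and UGT76B1 (0.07, 2) failed without WT 0 h R2. CBP60G (0.36, 4) failed without WT 0 h R1. HA8 (0.25, 4) failed without zed1-D 0 h R2.

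After 3 h at 28 °C salicylic-acid and pattern-triggered defence genes were higher in zed1-D. PR2, a secreted glucanase, was higher (394 ± 6.16 against 56.8 ± 3.67 CPM, 2.79 ± 0.14, FDR 1.9e-06), as were PR1 (165 ± 43.1 against 10.2 ± 4.1 CPM, 3.97 ± 0.44, FDR 3e-04) and PBS3 of salicylic acid synthesis (3.51 ± 0.22, FDR 7.2e-06). The same held for FMO1 (4.3 ± 0.27, FDR 7.2e-06) and CBP60G (2.64 ± 0.17, FDR 7.2e-06). PAD3 (4.01 ± 0.23, FDR 4.5e-06) and the transcription factors WRKY53 (2.9 ± 0.18, FDR 7.2e-06), WRKY46 (3.23 ± 0.28, FDR 6e-05) and WRKY33 (1.86 ± 0.16, FDR 5.1e-05) were higher too. The largest fold changes included AT3G28510, read at 3 or fewer counts in WT (30.7 ± 4.6 against 0.255 ± 0.0354 CPM, FDR 3.9e-05), AT3G13610 (5.15 ± 0.27, FDR 1.9e-06) and AT5G25260 (4.41 ± 0.37, FDR 5.1e-05). Lower genes included DR4 (-2.1 ± 0.23, FDR 0.00033), the cytokinin phosphotransfer gene AHP4 (-1.96 ± 0.32, FDR 0.0045) and HA8 (-1.39 ± 0.28, FDR 0.019).

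Among immune receptors at 3 h the helper genes ADR1-L2 (1.2 ± 0.16, FDR 0.0013), ADR1-L1 (1.06 ± 0.17, FDR 0.0041) and ADR1 (0.92 ± 0.15, FDR 0.0054) were higher. ZAR1 was higher (0.79 ± 0.18, FDR 0.039), while SNC1 did not pass (0.41 ± 0.14, FDR 0.22, blocked 0.00051). The chaperone BIP3 (3.39 ± 0.53, FDR 0.0034) and the calreticulin CRT3 (1.31 ± 0.28, FDR 0.029) were higher, as were the senescence-associated genes SAG21 (3.54 ± 0.18, FDR 1.9e-06) and SAG13 (2.97 ± 0.28, FDR 1e-04). The thionin THI2.1 (1.74 ± 0.23, FDR 0.0012) and the defensin PDF1.2A (1.85 ± 0.37, FDR 0.018) were the higher members of the jasmonate list. In the heat shock list HSP70-4 was higher (0.97 ± 0.23, FDR 0.048) and GOLS1, a galactinol synthase, lower (-1.15 ± 0.2, FDR 0.0078). MYB28 (-0.71 ± 0.14, FDR 0.015) and BCAT4 (-0.54 ± 0.11, FDR 0.017) of aliphatic glucosinolate synthesis and GLK2, a regulator of chloroplast development (-0.57 ± 0.12, FDR 0.032), were lower.

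By list at 3 h, the upward shifts were salicylic-acid defence (18 higher of 22, list alone 20 higher, median 2.49, FDR 1.4e-110, estimated 6.5e-05), pattern-triggered and camalexin (10 higher of 18, list alone 13 higher and 1 lower, median 1.82, FDR 3.1e-40, estimated 6.6e-05) and senescence (2 higher of 11, list alone 5 higher, blocked 5 higher and 1 lower, median 1.04, FDR 2.4e-11, estimated 0.0014). Glucosinolate genes shifted down (2 lower of 13, list alone 8 lower, blocked 9 lower, median -0.52, FDR 1.4e-06, estimated 0.018). Immune receptors (7 higher of 25, list alone 8 higher, blocked 13 higher, median 0.31, FDR 4.7e-06, estimated 0.13), ER chaperones (2 higher of 12, list alone 7 higher, blocked 12 higher, median 0.51, FDR 1.1e-06, estimated 0.12, blocked estimated 0.016) and pollen markers (0 of 5, list alone 2 higher, blocked 2 higher, median 0.79, FDR 0.045, estimated 0.15, blocked FDR 0.16) passed upward only with the preset correlation. Leaf photosynthesis (1 lower of 28, blocked 28 lower, median -0.47, FDR 2.5e-06, estimated 0.37) and warm-temperature growth (0 of 18, blocked 3 lower, median -0.21, FDR 0.035, estimated 0.092, blocked FDR 0.085) passed downward only with it. Not passing were heat shock (0.45, FDR 0.098, blocked 0.0077), tapetum (0.49, FDR 0.085), jasmonate (0.16, FDR 0.48), cold response (-0.05, FDR 0.6), clock (-0.05, FDR 0.47), cell cycle (0.07, FDR 0.6) and floral identity (0.19, FDR 0.69). For reference genes the test pointed down against a median above 0 (0.06, FDR 0.9). In the warm-growth and pollen lists edgeR gave an unadjusted p under 0.05 for 4 and 2 genes, and DESeq2 called 0.

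At 3 h 591 genes passed, 546 higher and 45 lower in zed1-D. The count was 3304 (1552 lower) blocked, 145 (1 lower) in the compared groups alone, 663 (84 lower) with DESeq2, 561 (23 lower) with no filter, 499 (27 lower) thinned and 487 (16 lower) with the fold minimum. With 1 library left out it was 376 and 309 without WT 3 h R1 or R2, 398 and 367 without zed1-D 3 h R1 or R2, 11 to 17 lower. ADR1 (0.053, 2), ADR1-L1 (0.056, 1), AHP4 (0.078, 2), GOLS1 (0.09, 3), MYB28 (0.13, 4) and PDF1.2A (0.2, 3) failed without WT 3 h R2. BCAT4 (0.17, 4), GLK2 (0.27, 4), HA8 (0.24, 3) and HSP70-4 (0.45, 3) failed without zed1-D 3 h R2. CRT3 (0.27, 3) and ZAR1 (0.3, 4) failed without WT 3 h R1.

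At 12 h the jasmonate list had joined the defence lists among genes higher in zed1-D. The jasmonate repressor genes JAZ5 (49.2 ± 0.579 against 7.33 ± 0.925 CPM, 2.76 ± 0.23, FDR 2.4e-05), JAZ1 (2.21 ± 0.2, FDR 3.5e-05) and JAZ9 (1.64 ± 0.11, FDR 1e-05) were higher. PDF1.2A was higher (22 ± 1.63 against 0.108 ± 0.152 CPM, FDR 7.6e-06) with at most 1 count in a WT library. MDHAR (7.25 ± 0.55, FDR 1.5e-05), NATA1 (5.97 ± 0.61, FDR 9.1e-05), AT3G16530 (4.92 ± 0.23, FDR 1.8e-06) and AT4G16260 (4.89 ± 0.36, FDR 1.2e-05) were among the largest fold changes. EDS5, which exports isochorismate from chloroplasts, was higher (2.97 ± 0.17, FDR 3.9e-06), with PR2 (2.58 ± 0.14, FDR 3.9e-06), CBP60G (2.41 ± 0.16, FDR 7.6e-06) and PAD4 (2.32 ± 0.16, FDR 8.3e-06). So were the camalexin genes PAD3 (3.63 ± 0.21, FDR 5.1e-06) and CYP71A13 (3.59 ± 0.29, FDR 2.2e-05) and their regulator WRKY33 (2.56 ± 0.16, FDR 5.2e-06). PR1 did not pass at this time (385 ± 99.8 against 164 ± 43.2 CPM, 1.23 ± 0.38, FDR 0.072, blocked 7.7e-16).

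Members of other lists also differed at 12 h. ADR1-L2 (1.26 ± 0.16, FDR 0.00041), ADR1 (1.16 ± 0.15, FDR 0.00049), ADR1-L1 (1.24 ± 0.17, FDR 0.00064) and ZAR1 (0.71 ± 0.18, FDR 0.028) were higher, and SNC1 did not pass (0.34 ± 0.14, FDR 0.19, blocked 0.0013). GOLS1 (2.86 ± 0.22, FDR 1.5e-05), HSP70-4 (2.11 ± 0.22, FDR 0.00011) and HSP17.8 (2.02 ± 0.41, FDR 0.0084) were higher in the heat shock list. So were CRT3 (1.49 ± 0.28, FDR 0.0057), BIP3 (2.59 ± 0.51, FDR 0.0066) and PDIL1-1 (0.75 ± 0.17, FDR 0.017) among ER chaperones, and SAG21 (2.82 ± 0.17, FDR 5.1e-06) and SAG13 (2.55 ± 0.25, FDR 6.1e-05) in senescence. Aliphatic glucosinolate genes CYP79F1 (-1.76 ± 0.16, FDR 3.5e-05), BCAT4 (-1.48 ± 0.11, FDR 1.4e-05) and MAM1 (-1.43 ± 0.16, FDR 0.00015) were lower while CYP79B3 of indole glucosinolate synthesis was higher (1.56 ± 0.16, FDR 9.1e-05). Photosynthesis-related genes GLK2 (-0.74 ± 0.13, FDR 0.0028), RBCS2B (-0.62 ± 0.15, FDR 0.019) and PORB (-0.72 ± 0.17, FDR 0.02) were lower. So were PIF4 (-0.83 ± 0.21, FDR 0.028), COR15B (-0.64 ± 0.18, FDR 0.046), the nicotianamine synthase NAS1 (-1.95 ± 0.33, FDR 0.0027) and UMAMIT36 (-1.85 ± 0.26, FDR 9e-04). The floral genes SEP2 (0.91 ± 0.2, FDR 0.014) and SEP1 (0.88 ± 0.22, FDR 0.028) and the pollen genes VGD1 (2.38 ± 0.22, FDR 5e-05) and VGDH1 (2.19 ± 0.56, FDR 0.03) were higher.

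By list at 12 h, upward shifts held for salicylic-acid defence (19 higher of 22, list alone 22 higher, median 2.22, FDR 3.4e-52, estimated 0.00037), pattern-triggered and camalexin (12 higher of 18, list alone 15 higher, median 2.1, FDR 1.4e-28, estimated 6.5e-05) and jasmonate (14 higher of 18, median 1.43, FDR 4.2e-22, estimated 0.021). They also held for senescence (4 higher of 11, list alone 6 higher, blocked 7 higher and 1 lower, median 1.39, FDR 2.1e-06, estimated 0.0071) and pollen markers (2 higher of 5, list alone 3 higher, median 1.73, FDR 0.0013, estimated 0.031, blocked estimated 0.1). Glucosinolate genes shifted down (3 higher and 7 lower of 13, list alone 3 higher and 8 lower, median -1.2, FDR 1.7e-05, estimated 0.031). Passing upward only with the preset correlation were heat shock (6 higher of 20, list alone 8 higher, blocked 12 higher, median 1.17, FDR 4.7e-06, estimated 0.29), ER chaperones (4 higher of 12, list alone 8 higher, blocked 12 higher, median 0.52, FDR 0.00086, estimated 0.29) and immune receptors (7 higher of 25, list alone 8 higher, blocked 13 higher, median 0.4, FDR 0.00061, estimated 0.26). Downward only with it were leaf photosynthesis (3 lower of 28, blocked 28 lower, median -0.5, FDR 4.8e-05, estimated 0.44) and warm-temperature growth (1 lower of 18, blocked 1 higher and 4 lower, median -0.36, FDR 0.03, estimated 0.085, blocked FDR 0.092). Cold response (-0.37, FDR 0.3), cell cycle (-0.17, FDR 0.06), floral identity (0.48, FDR 0.29) and clock (-0.21, FDR 0.17) did not pass. Tapetum (0.01, FDR 0.7) and reference genes (0.03, FDR 0.9) had tests pointing down against medians above 0.

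At 12 h 1871 genes passed, 1520 higher and 351 lower in zed1-D. The count was 6783 (2959 lower) blocked, 732 (26 lower) in the compared groups alone and 1268 (83 lower) with the fold minimum. Leaving out 1 library gave 1099 and 939 without WT 12 h R1 or R2, 1278 and 1165 without zed1-D 12 h R1 or R2, 118 to 157 lower. BIP3 (0.074, 2), HSP17.8 (0.084, 3), PORB (0.15, 3), SEP2 (0.13, 3) and ZAR1 (0.24, 3) failed without zed1-D 12 h R2. COR15B (0.23, 4) failed without zed1-D 12 h R1. CRT3 (0.08, 2) and PIF4 (0.17, 3) failed without WT 12 h R1. PDIL1-1 (0.15, 3), RBCS2B (0.1, 4), SEP1 (0.26, 4) and VGDH1 (0.34, 4) failed without WT 12 h R2.

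At 48 h defence genes were again higher in zed1-D, while cold-response, tapetum, glucosinolate and some jasmonate genes were lower. PR2 (2335 ± 33.1 against 102 ± 9.47 CPM, 4.52 ± 0.15, FDR 1.2e-07), PR4 (5.06 ± 0.22, FDR 4.7e-07), PR1 (3.39 ± 0.42, FDR 0.00029), CBP60G (3.32 ± 0.17, FDR 9e-07) and PAD4 (2.87 ± 0.16, FDR 1.5e-06) were higher. So were KTI1, a protease inhibitor (5.14 ± 0.26, FDR 9e-07), and ARD3 (5.04 ± 0.56, FDR 0.00014). PDF1.2A was higher (5.04 ± 0.32, FDR 3e-06) while the vegetative storage protein genes VSP2 (-2.29 ± 0.3, FDR 0.00049) and VSP1 (-1.91 ± 0.3, FDR 0.0015) were lower. COR15A (21.3 ± 4.66 against 148 ± 11.9 CPM, -2.78 ± 0.21, FDR 1.1e-05), COR15B (-2.13 ± 0.18, FDR 2.4e-05), COR414-TM1 (-2.5 ± 0.39, FDR 0.0014) and RD29A (-1.95 ± 0.38, FDR 0.0059) of the cold response were lower. AT5G37940 was read at 3 or fewer counts in zed1-D (0.133 ± 0.188 against 48.3 ± 2.69 CPM, FDR 5.1e-07). The anthocyanin genes AT5MAT (-4.83 ± 0.46, FDR 4.9e-05) and TT8 (-4.24 ± 0.34, FDR 1.6e-05) and DR4 (-3.94 ± 0.25, FDR 2.9e-06) were also lower.

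Growth and flower genes were lower at 48 h in part. The division genes HINKEL (-0.71 ± 0.16, FDR 0.011), CYCB1;2 (-0.8 ± 0.2, FDR 0.022) and CDKB2;1 (-0.82 ± 0.22, FDR 0.028) were lower, as were the meristem and floral genes KNAT1 (-0.57 ± 0.13, FDR 0.012), ANT (-0.77 ± 0.18, FDR 0.015) and AP1 (-0.76 ± 0.23, FDR 0.046). The tapetum genes MS2 (-1.26 ± 0.27, FDR 0.0099), LAP5 (-1.35 ± 0.3, FDR 0.011) and A6 (-2.11 ± 0.5, FDR 0.016) were lower. So were VGD1 (-0.77 ± 0.2, FDR 0.022), PRE1 (-1.3 ± 0.3, FDR 0.014), the brassinosteroid synthesis gene DWF4 (-1.12 ± 0.27, FDR 0.017), PSBP1 (-0.63 ± 0.16, FDR 0.021) and PETE2 (-0.48 ± 0.13, FDR 0.036), while PIF5 was higher (1.03 ± 0.16, FDR 0.0015). The morning clock genes LHY (2.02 ± 0.29, FDR 0.00091), RVE1 (1.83 ± 0.21, FDR 2e-04) and CCA1 (1.66 ± 0.32, FDR 0.0049) were higher and FKF1 was lower (-1.05 ± 0.19, FDR 0.0036). MYB29 (-2.91 ± 0.3, FDR 8.8e-05), MYB28 (-1.09 ± 0.14, FDR 0.00042), BCAT4 (-1.57 ± 0.11, FDR 6.4e-06) and CYP79F1 (-1.39 ± 0.15, FDR 0.00014) of the glucosinolate list were lower.

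Stress and immune genes higher at 48 h included WRKY53 (2.59 ± 0.17, FDR 4.3e-06), WRKY46 (3.48 ± 0.28, FDR 1.5e-05), PAD3 (3 ± 0.23, FDR 1.2e-05), ADR1 (1.45 ± 0.15, FDR 1e-04) and ADR1-L1 (1.51 ± 0.17, FDR 0.00016). ZAR1 (0.21 ± 0.18, FDR 0.53) and SNC1 (0.32 ± 0.14, FDR 0.17, blocked 0.0023) did not pass. The chaperones BIP3 (3.71 ± 0.53, FDR 0.00083), CRT3 (1.68 ± 0.29, FDR 0.0025), CNX1 (0.81 ± 0.13, FDR 0.0017) and the heat shock factor HSFB2A (1.27 ± 0.24, FDR 0.0052) were higher. In the senescence list SAG13 (4.08 ± 0.27, FDR 4.1e-06), SAG21 (3.51 ± 0.18, FDR 9e-07) and SEN1 (3.24 ± 0.36, FDR 0.00014) were higher.

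By list at 48 h, salicylic-acid defence (19 higher of 22, list alone 20 higher, median 2.78, FDR 2.7e-46, estimated 0.00047), pattern-triggered and camalexin (11 higher of 18, list alone 13 higher, median 1.5, FDR 1.3e-14, estimated 0.00056) and senescence (6 higher of 11, median 2.01, FDR 3.9e-11, estimated 0.0014) shifted up. Cold response (4 lower of 7, blocked 7 lower, median -1.95, FDR 4.6e-08, estimated 0.0036) and tapetum (6 lower of 10, list alone 9 lower, median -1.29, FDR 4.5e-05, estimated 0.031, blocked estimated 0.15) shifted down. So did cell cycle (3 lower of 22, blocked 13 lower, median -0.38, FDR 0.0028, estimated 0.031, blocked estimated 0.17) and glucosinolate (2 higher and 7 lower of 13, list alone 2 higher and 8 lower, median -0.72, FDR 2.1e-05, estimated 0.031). Immune receptors (7 higher of 25, blocked 11 higher, median 0.32, FDR 0.0021, estimated 0.29) and ER chaperones (6 higher of 12, list alone 10 higher, blocked 12 higher, median 0.85, FDR 1.5e-05, estimated 0.17, blocked estimated 0.04) passed upward only with the preset correlation. Jasmonate (-0.43, FDR 0.31, blocked 0.0065, blocked estimated 0.045), heat shock (0.13, FDR 0.14), warm-temperature growth (-0.14, FDR 0.5), floral identity (-0.35, FDR 0.06), and pollen (-0.4, FDR 0.27) did not pass. Neither did leaf photosynthesis (-0.38, FDR 0.12, blocked 0.0036), clock (0.02, FDR 0.27) or reference genes (0.16, FDR 0.88).

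At 48 h 2812 genes passed, 1607 higher and 1205 lower in zed1-D. The count was 8807 (4542 lower) blocked, 1322 (368 lower) in the compared groups alone and 1642 (548 lower) with the fold minimum. With 1 library left out it was 1657 and 1417 without WT 48 h R1 or R2, 1796 and 1492 without zed1-D 48 h R1 or R2, 469 to 680 lower. A6 (0.15, 3), CDKB2;1 (0.18, 4), KNAT1 (0.1, 3) and LAP5 (0.12, 2) failed without zed1-D 48 h R2. ANT (0.12, 2), AP1 (0.27, 4), CCA1 (0.052, 1), DWF4 (0.14, 3), HINKEL (0.092, 2), HSFB2A (0.08, 1), MS2 (0.096, 2) and PRE1 (0.097, 4) failed without WT 48 h R2. CYCB1;2 (0.18, 3), PETE2 (0.25, 4), PSBP1 (0.2, 3) and VGD1 (0.19, 3) failed without WT 48 h R1. RD29A (0.058, 1) failed without zed1-D 48 h R1.

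**Figure D2:**
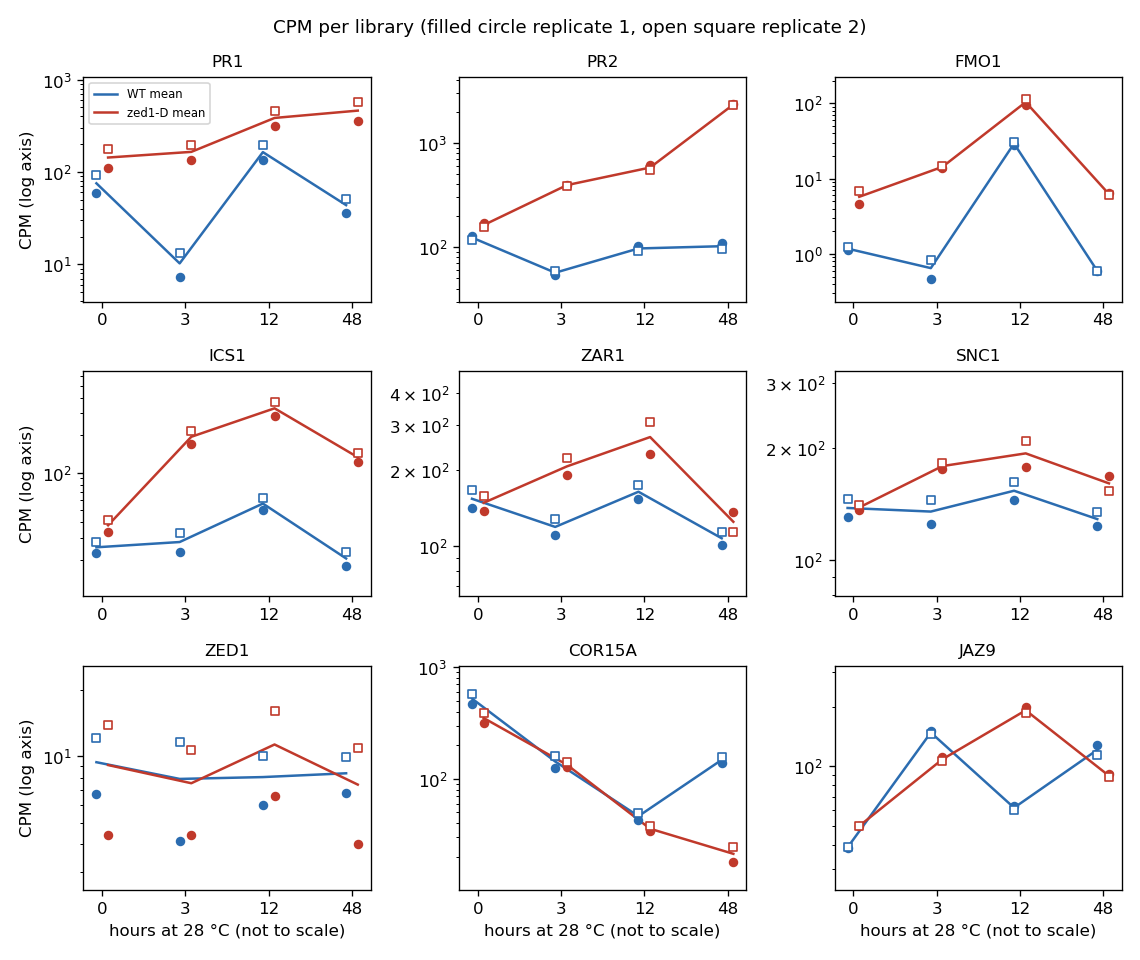
Expression of PR1, PR2, FMO1, ICS1, ZAR1, SNC1, ZED1, COR15A and JAZ9 in CPM on log axes against hours at 28 °C, not to scale. Points are single libraries, filled for replicate 1 and open for replicate 2, and lines join the means of 2.

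**Figure D3:**
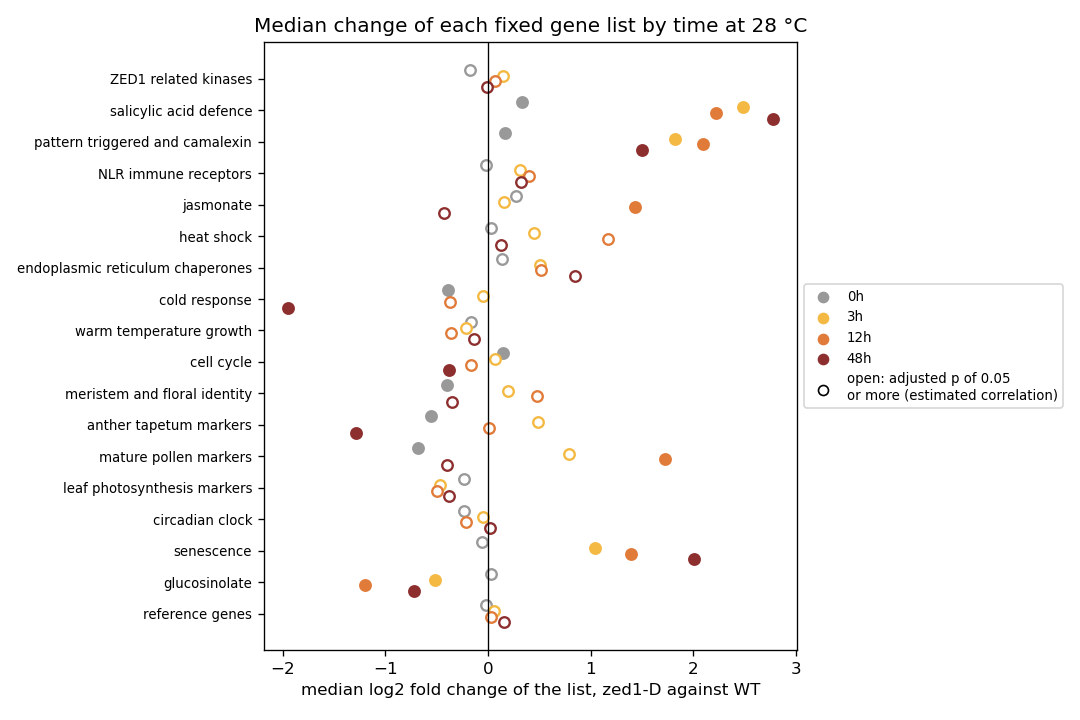
Median log2 fold change of each fixed gene list, zed1-D against WT, at 0, 3, 12 and 48 h, 1 colour per time. Filled points had an adjusted p under 0.05 with an estimated correlation and no block, and the salicylic-acid list did at all 4 times.

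Genotype differences overlapped between times. Of genes higher in zed1-D, 521 passed at 3 and 12 h against 43 expected if independent. For 3 and 48 h it was 482 against 45.4, for 12 and 48 h 931 against 126.5. For lower genes the counts were 29 against 0.8, 33 against 2.8 and 179 against 21.9. At all 3 later times 466 were higher and 22 lower. Times use different libraries but the same gene variances, so expected counts may be low.

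In WT cold-response and defence genes fell by 3 h at 28 °C. Time of day and age were not separated from temperature, for lack of later unmoved plants. The clock list passed even at 48 h, nominally whole days. COR15B (-2.63 ± 0.18, FDR 5.6e-05), COR15A (-1.87 ± 0.2, FDR 0.001) and RD29A (-2.24 ± 0.38, FDR 0.012) fell. Among defence genes so did WRKY70 (-1.21 ± 0.13, FDR 0.001), PR2 (-1.12 ± 0.13, FDR 0.0017), PR1 (-2.84 ± 0.42, FDR 0.0058), MPK11 (-2.16 ± 0.29, FDR 0.0036), PAD3 (-1.44 ± 0.24, FDR 0.01) and SAG21 (-1.59 ± 0.18, FDR 0.0011). PORA, a light-repressed chlorophyll synthesis gene, fell (-3.01 ± 0.35, FDR 0.0016), and so did the tapetum gene A9 (-1.29 ± 0.28, FDR 0.043). HSP70-4 (2.51 ± 0.28, FDR 0.0011), GOLS1 (2.24 ± 0.22, FDR 0.00055), JAZ9 (1.93 ± 0.12, FDR 3.4e-05) and AOC1 (2.33 ± 0.29, FDR 0.0023) rose. So did PIF5 (0.85 ± 0.16, FDR 0.023), RBCS2B (1.13 ± 0.15, FDR 0.0028) and CYP79B3 (1.19 ± 0.16, FDR 0.0036). The clock genes RVE8 (3.72 ± 0.44, FDR 0.0016), RVE1 (1.75 ± 0.24, FDR 0.0036) and LHY (2.97 ± 0.43, FDR 0.0053) rose. The iron-response gene BHLH100 rose (8.46 ± 3.2 against 0.234 ± 0.197 CPM, FDR 0.0025) with at most 2 counts at 0 h.

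By list, WT at 3 h had salicylic-acid defence (6 of 22, blocked 17, median -0.84, FDR 2e-18, estimated 0.0052), pattern-triggered and camalexin (5 of 18, blocked 2 higher and 10 lower, median -0.75, FDR 3.2e-06, estimated 0.0048, blocked estimated 0.059), cold response (4 of 7, blocked 7, median -1.82, FDR 2.2e-21, estimated 0.00048) and senescence (2 of 11, blocked 4, median -0.68, FDR 3e-04, estimated 0.017, blocked estimated 0.084) down and clock genes up (4 higher and 1 lower of 14, blocked 6 higher and 3 lower, median 0.26, FDR 6.9e-06, estimated 0.024, blocked estimated 0.096). Upward only with the preset correlation were jasmonate (5 of 18, blocked 10 higher and 1 lower, FDR 2.5e-10, estimated 0.079, blocked estimated 0.0026), heat shock (2 of 20, blocked 6, FDR 5.2e-05, estimated 0.32) and leaf photosynthesis (2 of 28, blocked 13 higher and 5 lower, FDR 0.013, estimated 0.62). Downward only with it were cell cycle (0 of 22, unadjusted 3, DESeq2 0, blocked 1 higher and 6 lower, FDR 0.014, estimated 0.052), floral identity (0 of 22, unadjusted 3, DESeq2 0, blocked 6, FDR 0.0077, estimated 0.15), tapetum (1 of 10, blocked 3, FDR 0.0028, estimated 0.071) and pollen (0 of 5, unadjusted 2, DESeq2 0, blocked 2, FDR 0.0048, estimated 0.053). In all 343 genes passed in WT at 3 h, 162 higher and 181 lower than at 0 h. The count was 3912 (2106 lower) blocked, 0 in the compared groups alone, 548 (296 lower) with DESeq2 and 210 (108 lower) with the fold minimum, with 1077 genes at an unadjusted p under 0.05 in edgeR on the compared groups. It was 118 and 110 without WT 0 h R1 or R2, 120 and 114 without WT 3 h R1 or R2, 53 to 63 lower. A9 (0.23, 4), PR1 (0.066, 1) and RD29A (0.11, 2) failed without WT 3 h R1. BHLH100 (0.065, 1), CYP79B3 (0.056, 1), PIF5 (0.2, 3) and RVE1 (0.066, 1) failed without WT 0 h R2. LHY (0.052, 1) and PAD3 (0.12, 4) failed without WT 3 h R2.

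After 12 h WT cold-response genes remained low and part of the salicylic-acid list was raised. COR15A (-3.49 ± 0.22, FDR 1.5e-05), COR15B (-2.88 ± 0.19, FDR 2e-05) and KIN1 (-3.1 ± 0.43, FDR 0.0063) fell. Among other genes so did LHCB1.1, a light-harvesting gene (-3.78 ± 0.64, FDR 0.016), PORA (-4.06 ± 0.38, FDR 5e-04), SEP2 (-0.97 ± 0.2, FDR 0.042) and VGD1 (-1.53 ± 0.23, FDR 0.008). FMO1 (4.6 ± 0.25, FDR 9.5e-06), CBP60G (1.26 ± 0.16, FDR 0.0039), ALD1 (1.86 ± 0.3, FDR 0.013) and CYP71A13 (2.01 ± 0.3, FDR 0.008) rose. So did HSP70-4 (3.61 ± 0.27, FDR 8.9e-05), HSP101 (1.03 ± 0.22, FDR 0.044), JAZ9 (0.66 ± 0.11, FDR 0.017) and PRR5 (0.76 ± 0.16, FDR 0.045), and BHLH100 rose (27.7 ± 8.69 against 0.234 ± 0.197 CPM, FDR 0.00045). PR1 did not pass (1.12 ± 0.38, FDR 0.24, blocked 1e-12).

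By list, WT at 12 h had salicylic-acid defence (7 of 22, blocked 9 higher and 3 lower, median 0.22, FDR 1.1e-09, estimated 0.024), pattern-triggered and camalexin (2 of 18, blocked 9, median 0.25, FDR 1.2e-06, estimated 0.0038) and warm-temperature growth (0 of 18, unadjusted 5, DESeq2 1, blocked 4, median 0.42, FDR 0.0034, estimated 0.031, blocked estimated 0.06) up. Cold response (4 of 7, blocked 7, median -2.03, FDR 1.6e-31, estimated 0.00017), cell cycle (0 of 22, unadjusted 8, DESeq2 0, blocked 1 higher and 11 lower, median -0.4, FDR 4.5e-05, estimated 0.0079), floral identity (1 of 22, blocked 9, median -0.47, FDR 3.8e-05, estimated 0.043), tapetum (0 of 10, unadjusted 3, DESeq2 0, blocked 4, median -0.57, FDR 0.00059, estimated 0.037, blocked estimated 0.13) and pollen markers (1 of 5, blocked 2, median -1.33, FDR 2.9e-05, estimated 0.012, blocked estimated 0.054) were down. Passing upward with the preset alone were heat shock (2 of 20, blocked 8, FDR 4.7e-07, estimated 0.21, blocked estimated 0.044), immune receptors (0 of 25, unadjusted 3, DESeq2 0, blocked 5, FDR 0.0077, estimated 0.35), jasmonate (1 higher and 1 lower of 18, blocked 11 higher and 1 lower, FDR 0.0024, estimated 0.38, blocked estimated 0.016) and clock (1 of 14, blocked 6, FDR 8e-04, estimated 0.061).

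In all 292 genes passed in WT at 12 h, 159 higher and 133 lower. The count was 4107 (2103 lower) blocked, 0 in the compared groups alone, 480 (230 lower) with DESeq2, 205 (84 lower) with no filter and 159 (49 lower) with the fold minimum, with 1136 genes at an unadjusted p under 0.05 in edgeR on the compared groups. It was 61 and 65 without WT 0 h R1 or R2, 63 and 54 without WT 12 h R1 or R2, 15 to 29 lower. ALD1 (0.13, 4) failed without WT 0 h R2. CYP71A13 (0.092, 2), HSP101 (0.3, 4), KIN1 (0.11, 1), LHCB1.1 (0.17, 3) and VGD1 (0.13, 4) failed without WT 12 h R2. JAZ9 (0.16, 4) and PRR5 (0.26, 4) failed without WT 0 h R1. SEP2 (0.25, 4) failed without WT 12 h R1.

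After 48 h WT showed raised jasmonate genes and lower cold-response and division genes. THI2.1 (2.81 ± 0.22, FDR 0.00013), JAZ9 (1.64 ± 0.12, FDR 4.1e-05), HSP70-4 (3.88 ± 0.27, FDR 4.1e-05), GOLS1 (1.44 ± 0.22, FDR 0.0068) and the auxin-response gene SAUR20 (1.74 ± 0.32, FDR 0.015) rose. So did LHY (3.9 ± 0.41, FDR 0.00061), CCA1 (2.63 ± 0.44, FDR 0.011) and VGD1 (1.4 ± 0.2, FDR 0.0046). AT2G14247 (6.7 ± 0.57, FDR 0.00018) and AT1G13609 (6.08 ± 0.6, FDR 0.00043) had large increases, and BHLH100 rose (105 ± 27.9 against 0.234 ± 0.197 CPM, FDR 4.1e-05). COR15B (-1.81 ± 0.18, FDR 0.00044), COR15A (-1.82 ± 0.2, FDR 0.00086), HINKEL (-1.05 ± 0.15, FDR 0.0048) and CYCB1;1 (-0.96 ± 0.17, FDR 0.014) fell. Lower too were PAD3 (-1.48 ± 0.24, FDR 0.0085), LHCB1.1 (-5.56 ± 0.7, FDR 0.002), LHCB3 (-1.94 ± 0.29, FDR 0.0062), BG3 (-2.29 ± 0.27, FDR 0.0013) and the chlorophyll breakdown gene NYC1 (-1.22 ± 0.12, FDR 0.00047). PR1 did not pass (-0.78 ± 0.38, FDR 0.37, blocked 2.3e-08).

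By list, WT at 48 h had jasmonate (7 of 18, blocked 13, median 0.87, FDR 2.3e-16, estimated 0.033), clock (6 higher and 1 lower of 14, blocked 8 higher and 2 lower, median 0.6, FDR 1.7e-06, estimated 0.019, blocked estimated 0.12), warm-temperature growth (1 of 18, blocked 9, median 0.56, FDR 0.00023, estimated 0.013, blocked estimated 0.059) and pollen markers (1 of 5, blocked 3, median 0.98, FDR 0.0012, estimated 0.033, blocked estimated 0.07) up. Cold response (2 of 7, blocked 5, median -1.37, FDR 7.7e-10, estimated 0.0023), cell cycle (2 of 22, blocked 1 higher and 14 lower, median -0.53, FDR 9.8e-07, estimated 0.0035) and pattern-triggered and camalexin (2 of 18, blocked 2 higher and 8 lower, median -0.33, FDR 0.0059, estimated 0.037, blocked estimated 0.17) were down. Upward with the preset alone were heat shock (2 of 20, blocked 8 higher and 1 lower, FDR 1.5e-06, estimated 0.22) and floral identity (1 of 22, blocked 8 higher and 1 lower, FDR 0.031, estimated 0.26). Downward with it alone were leaf photosynthesis (2 higher and 4 lower of 28, blocked 5 higher and 19 lower, FDR 8.2e-05, estimated 0.42, blocked estimated 0.048) and salicylic-acid defence (0 of 22, unadjusted 7, DESeq2 0, blocked 14, FDR 2.2e-05, estimated 0.08, blocked estimated 0.015). In all 574 genes passed in WT at 48 h, 343 higher and 231 lower. The count was 5675 (2943 lower) blocked, 5 (0 lower) in the compared groups alone and 310 (84 lower) with the fold minimum. Leaving out 1 library gave 132 and 95 without WT 0 h R1 or R2, 126 and 168 without WT 48 h R1 or R2, 33 to 46 lower. CCA1 (0.13, 4), GOLS1 (0.09, 2) and VGD1 (0.068, 2) failed without WT 0 h R2. CYCB1;1 (0.12, 4), LHCB3 (0.069, 2) and PAD3 (0.084, 2) failed without WT 48 h R2. HINKEL (0.067, 2) failed without WT 48 h R1. SAUR20 (0.12, 4) failed without WT 0 h R1.

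In zed1-D salicylic-acid genes rose by 3 h at 28 °C. ICS1, the first enzyme of salicylic acid synthesis (194 ± 33.3 against 37.9 ± 6.02 CPM, 2.35 ± 0.25, FDR 0.001), EDS5 (1.72 ± 0.16, FDR 0.00054), PR2 (1.27 ± 0.13, FDR 0.001) and WRKY46 (2.23 ± 0.26, FDR 0.0017) rose. Also raised were HSP70-4 (2.07 ± 0.25, FDR 0.0017), HSP101 (1.28 ± 0.22, FDR 0.01) and the clock gene RVE8 (4.06 ± 0.46, FDR 0.0015). COR15B (-2.28 ± 0.18, FDR 0.00026), GRP7, an RNA-binding protein gene under clock control (-2.98 ± 0.2, FDR 1e-04), CYCA1;1 (-0.67 ± 0.15, FDR 0.044), BCAT4 (-0.78 ± 0.11, FDR 0.0034) and MAM1 (-0.95 ± 0.16, FDR 0.0089) fell. PR1 did not pass (0.2 ± 0.38, FDR 0.95). Of the lists, salicylic-acid defence (12 of 22, median 1.22, FDR 1.4e-31, estimated 0.002), pattern-triggered and camalexin (5 of 18, blocked 12, median 0.68, FDR 7.9e-11, estimated 0.0016), senescence (2 of 11, blocked 3 higher and 1 lower, median 0.45, FDR 4.6e-05, estimated 0.01) and clock (4 of 14, blocked 6 higher and 2 lower, median 0.15, FDR 1.2e-05, estimated 0.017, blocked estimated 0.068) went up. Cold response (2 of 7, blocked 7, median -1.11, FDR 2.6e-13, estimated 0.0016), cell cycle (1 of 22, blocked 1 higher and 11 lower, median -0.33, FDR 0.00017, estimated 0.012) and glucosinolate (3 of 13, blocked 2 higher and 9 lower, median -0.36, FDR 0.00022, estimated 0.046) went down. The preset alone passed, upward, immune receptors (4 of 25, blocked 17, FDR 3.7e-07, estimated 0.079), jasmonate (2 of 18, blocked 11, FDR 3.1e-06, estimated 0.17, blocked estimated 0.012), heat shock (3 of 20, blocked 9, FDR 6.9e-06, estimated 0.26, blocked estimated 0.048), ER chaperones (0 of 12, unadjusted 5, DESeq2 4, blocked 8, FDR 0.00031, estimated 0.22), tapetum (0 of 10, unadjusted 2, DESeq2 0, blocked 3, FDR 0.031, estimated 0.17, blocked 0.051) and pollen (1 of 5, blocked 2, FDR 0.029, estimated 0.11, blocked 0.21).

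In all 525 genes passed in zed1-D at 3 h, 390 higher and 135 lower. In the compared groups alone the count was 0, with 1771 genes at an unadjusted p under 0.05 in edgeR. It was 4608 (2135 lower) blocked, 671 (227 lower) with DESeq2 on all libraries and 394 (87 lower) with no filter. It was 369 (86 lower) thinned and 325 (48 lower) with the fold minimum. It was 122 and 127 without zed1-D 0 h R1 or R2, 204 and 146 without zed1-D 3 h R1 or R2, 22 to 33 lower. BCAT4 (0.054, 1) and MAM1 (0.11, 2) failed without zed1-D 3 h R2. CYCA1;1 (0.27, 4) failed without zed1-D 3 h R1. HSP101 (0.13, 4) failed without zed1-D 0 h R1.

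After 12 h zed1-D showed raised salicylic-acid and jasmonate genes. FMO1 (4.13 ± 0.21, FDR 2.5e-06), EDS5 (3.19 ± 0.17, FDR 2.5e-06), PR1 (1.42 ± 0.38, FDR 0.029), ADR1-L1 (1.5 ± 0.17, FDR 0.00016), ZAR1 (0.86 ± 0.18, FDR 0.0078) and SNC1 (0.49 ± 0.14, FDR 0.038) rose. JAZ9 (1.94 ± 0.12, FDR 4.7e-06), the jasmonate-regulated gene JRG21 (4.98 ± 0.27, FDR 2.8e-06) and the chaperone genes HSP90.1 (4.78 ± 0.72, FDR 0.001), HSP70-4 (4.3 ± 0.25, FDR 4.7e-06), HSP101 (2.02 ± 0.22, FDR 0.00012) and CRT3 (1.52 ± 0.28, FDR 0.004) rose. COR15A (-3.29 ± 0.21, FDR 5.5e-06), CYCA1;1 (-1.25 ± 0.16, FDR 0.00027), HINKEL (-0.96 ± 0.15, FDR 0.0013), LHCB1.1 (-4.81 ± 0.67, FDR 0.00063), BCAT4 (-1.54 ± 0.11, FDR 9.2e-06) and CYP79F1 (-2.01 ± 0.16, FDR 1.4e-05) fell. Of the lists, salicylic-acid defence (20 of 22, median 2.25, FDR 6.1e-46, estimated 0.0012), pattern-triggered and camalexin (14 of 18, median 2.3, FDR 4.2e-25, estimated 0.00017), jasmonate (17 of 18, median 1.74, FDR 3e-20, estimated 0.024) and senescence (5 higher and 1 lower of 11, median 1.37, FDR 8.6e-06, estimated 0.0066) went up. Cold response (5 of 7, median -1.35, FDR 7.7e-10, estimated 0.0023), cell cycle (10 of 22, blocked 20, median -0.69, FDR 7e-08, estimated 0.0023) and glucosinolate (3 higher and 7 lower of 13, median -1.29, FDR 8.6e-06, estimated 0.024) went down. Up by the preset alone were heat shock (10 of 20, FDR 1.1e-09, estimated 0.13, blocked estimated 0.048), immune receptors (12 of 25, blocked 20, FDR 3e-06, estimated 0.11), ER chaperones (7 of 12, blocked 12, FDR 0.0018, estimated 0.29) and pollen (2 of 5, FDR 0.028, estimated 0.11, blocked 0.14). Leaf photosynthesis went down by it alone (1 higher and 3 lower of 28, blocked 3 higher and 21 lower, FDR 0.0011, estimated 0.51).

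In all 2863 genes passed in zed1-D at 12 h, 2017 higher and 846 lower. The count was 8485 (3771 lower) blocked, 1111 (137 lower) in the compared groups alone and 1687 (230 lower) with the fold minimum. With 1 library left out it was 1709 and 1565 without zed1-D 0 h R1 or R2, 1884 and 1738 without zed1-D 12 h R1 or R2, 382 to 491 lower. CRT3 (0.06, 1), PR1 (0.22, 3) and ZAR1 (0.095, 2) failed without zed1-D 0 h R1. SNC1 (0.27, 4) failed without zed1-D 12 h R2.

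After 48 h zed1-D had the most changed genes of any comparison with 0 h. PR2 (3.84 ± 0.15, FDR 2.5e-07), PAD4 (2.39 ± 0.16, FDR 4.6e-06), PR1 (1.69 ± 0.39, FDR 0.011) and PDF1.2A (4.85 ± 0.31, FDR 4.2e-06) rose. Also higher than at 0 h were the nitrilase NIT2 (5.26 ± 0.2, FDR 2.5e-07), SAG29 (4.32 ± 0.47, FDR 0.00012), PIF5 (1.04 ± 0.16, FDR 0.0012) and the expansin EXPA8 (1.36 ± 0.26, FDR 0.0041), with the clock genes LHY (6.25 ± 0.41, FDR 4.8e-06), RVE1 (3.26 ± 0.24, FDR 9.2e-06) and CCA1 (4.55 ± 0.42, FDR 4e-05). COR15A (-4.03 ± 0.22, FDR 2.3e-06), HINKEL (-2.16 ± 0.16, FDR 9.2e-06) and CYCB1;1 (-1.82 ± 0.18, FDR 5.2e-05) fell. Lower as well were ANT (-1.65 ± 0.18, FDR 0.00013), LAP5 (-1.48 ± 0.3, FDR 0.0051), PORB (-1.27 ± 0.17, FDR 0.00052), AT5MAT (-5.14 ± 0.46, FDR 3.4e-05) and TT8 (-4.93 ± 0.33, FDR 5.5e-06). Of the lists, salicylic-acid defence (15 higher and 1 lower of 22, median 1.82, FDR 6.3e-18, estimated 0.0052), pattern-triggered and camalexin (6 of 18, blocked 11 higher and 2 lower, median 0.63, FDR 0.00054, estimated 0.017), senescence (5 higher and 1 lower of 11, blocked 8 higher and 1 lower, median 1.83, FDR 2.1e-07, estimated 0.0035) and clock (6 higher and 2 lower of 14, median 0.28, FDR 2.8e-05, estimated 0.015) went up. Cold response (5 of 7, median -2.74, FDR 2.2e-12, estimated 0.0016) and cell cycle (15 of 22, median -1.02, FDR 2.7e-12, estimated 0.0017) went down, and so did glucosinolate (2 higher and 7 lower of 13, median -0.6, FDR 0.00022, estimated 0.05), by an estimated value just under the threshold. Lists up by the preset alone were heat shock (8 of 20, blocked 10 higher and 3 lower, FDR 0.00026, estimated 0.35), immune receptors (5 of 25, blocked 12 higher and 4 lower, FDR 0.044, estimated 0.46), jasmonate (3 of 18, blocked 7 higher and 2 lower, FDR 0.011, estimated 0.46), ER chaperones (4 of 12, blocked 9, FDR 0.015, estimated 0.42), warm-temperature growth (6 of 18, blocked 8 higher and 1 lower, FDR 0.028, estimated 0.079, blocked 0.051) and pollen (2 of 5, blocked 4, FDR 0.021, estimated 0.1, blocked 0.13). Those down were tapetum (4 of 10, blocked 1 higher and 7 lower, FDR 0.007, estimated 0.082, blocked 0.055) and leaf photosynthesis (2 higher and 7 lower of 28, blocked 6 higher and 19 lower, FDR 0.0047, estimated 0.58).

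In all 3870 genes passed in zed1-D at 48 h, 2066 higher and 1804 lower. The count was 10187 (5078 lower) blocked, 2203 (886 lower) in the compared groups alone and 2281 (880 lower) with the fold minimum. Leaving out 1 library gave 2332 and 1948 without zed1-D 0 h R1 or R2, 1994 without zed1-D 48 h R2, 738 to 998 lower. LAP5 (0.063, 1) and PR1 (0.094, 2) failed without zed1-D 48 h R2.

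**Figure D4:**
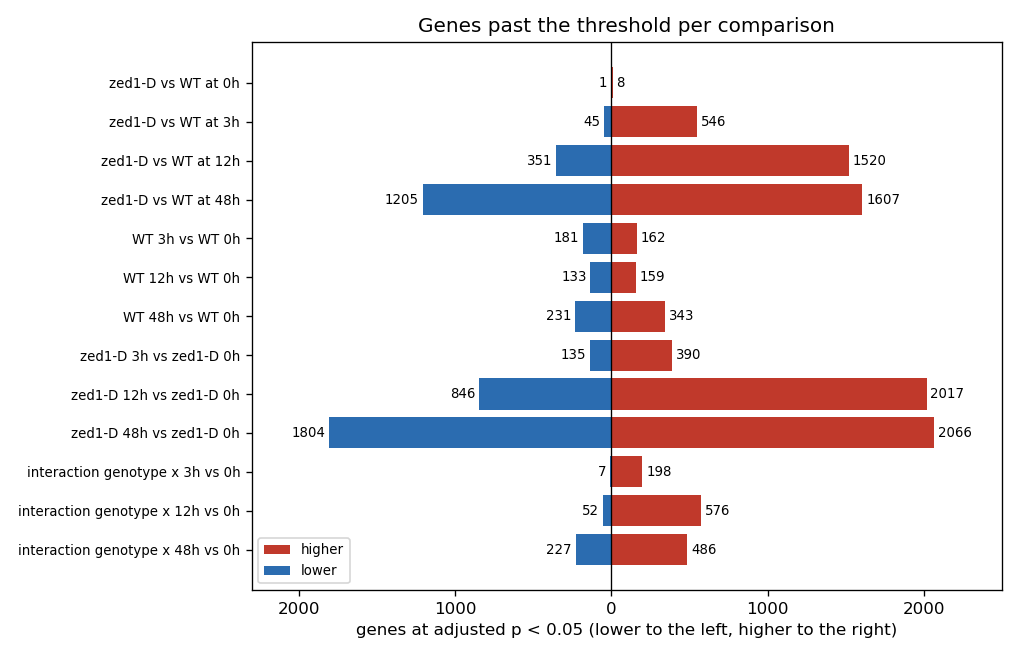
Number of genes passing in each comparison, split by direction, without the block. Bars to the right count genes higher in the first group, or with a positive interaction, and bars to the left lower genes, from 8 and 1 for zed1-D against WT at 0 h to 2066 and 1804 for zed1-D at 48 h against 0 h.

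Tests of the interaction asked where the change since 0 h differed between genotypes. At 3 h its value was positive for PR2 (2.39 ± 0.19, FDR 0.00036), PCR1 (2.66 ± 0.19, FDR 0.00023), AT5G52760 (3.77 ± 0.27, FDR 0.00023) and WRKY70 (1.9 ± 0.18, FDR 0.00072). SAG21 (2.93 ± 0.24, FDR 0.00036), VGD1 (1.47 ± 0.3, FDR 0.048) and PR1 (3.05 ± 0.56, FDR 0.026) were positive as well. Negative values held for PYK10 (-1.12 ± 0.16, FDR 0.0073), GOLS1 (-1.76 ± 0.3, FDR 0.018) and BCAT4 (-0.8 ± 0.15, FDR 0.033). Positive list interactions were salicylic-acid defence (15 of 22, median 2, FDR 1.3e-82, estimated 0.00012), pattern-triggered and camalexin (6 of 18, blocked 11, median 1.47, FDR 6e-26, estimated 0.00012), senescence (2 of 11, median 1.62, FDR 7.7e-12, estimated 0.00076), tapetum (0 of 10, unadjusted 4, DESeq2 0, blocked 4, median 0.97, FDR 9.6e-07, estimated 0.012) and pollen markers (2 of 5, median 1.47, FDR 1.7e-06, estimated 0.0062), and glucosinolate was negative (1 of 13, blocked 8, median -0.43, FDR 4.3e-07, estimated 0.012). Positive with the preset alone were immune receptors (1 of 25, blocked 10, FDR 1.7e-06, estimated 0.11), ER chaperones (0 of 12, unadjusted 2, DESeq2 1, blocked 8, FDR 5.8e-05, estimated 0.21, blocked estimated 0.023) and floral identity (0 of 22, unadjusted 4, DESeq2 0, blocked 4, FDR 0.0016, estimated 0.11, blocked estimated 0.034). Negative by it was leaf photosynthesis (0 of 28, unadjusted 1, DESeq2 0, blocked 3, FDR 0.0059, estimated 0.63). In all 205 genes passed, 198 positive and 7 negative. The count was 1093 (261 lower) blocked, 29 (0 lower) in the compared groups alone, 268 (15 lower) with DESeq2, 182 (4 lower) with no filter and 163 (4 lower) thinned. With 1 library left out it was 133 and 101 without WT 0 h R1 or R2, 113 and 109 without WT 3 h R1 or R2, 113 and 103 without zed1-D 0 h R1 or R2, 123 and 110 without zed1-D 3 h R1 or R2, 2 to 3 lower. BCAT4 (0.16, 8) failed without zed1-D 3 h R2. GOLS1 (0.12, 6) and VGD1 (0.2, 7) failed without zed1-D 0 h R2. PR1 (0.13, 6) failed without zed1-D 0 h R1.

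At 12 h the interaction was positive for FAMT (3.56 ± 0.22, FDR 8.9e-05), JRG21 (4.88 ± 0.4, FDR 0.00042), PR2 (2.18 ± 0.19, FDR 0.00056) and WRKY33 (2.37 ± 0.22, FDR 0.00056). It was also positive for ADR1-L2 (1.3 ± 0.23, FDR 0.0094), SEP2 (1.47 ± 0.28, FDR 0.017) and VGD1 (3.07 ± 0.31, FDR 7e-04). PDF1.2A also passed (FDR 0.00056). It was negative for BCAT4 (-1.73 ± 0.15, FDR 0.00056), NAS4 (-1.46 ± 0.19, FDR 0.0022) and ORG1 (-1.44 ± 0.17, FDR 0.0014), and PR1 did not pass (0.3 ± 0.53, FDR 1, blocked 0.049). Salicylic-acid defence (14 of 22, median 1.68, FDR 5.9e-34, estimated 0.00089), pattern-triggered and camalexin (6 of 18, blocked 14, median 1.5, FDR 8.3e-19, estimated 0.00017), jasmonate (7 of 18, blocked 15, median 1.28, FDR 5e-16, estimated 0.034), senescence (2 of 11, blocked 5, median 1.09, FDR 1.7e-06, estimated 0.004) and pollen markers (2 of 5, blocked 4, median 2.62, FDR 4.8e-08, estimated 0.003) were positive. In contrast cell cycle (0 of 22, unadjusted 3, DESeq2 1, blocked 5, median -0.34, FDR 0.00053, estimated 0.012) and glucosinolate (3 higher and 5 lower of 13, blocked 3 higher and 9 lower, median -1.05, FDR 2.4e-06, estimated 0.017) were negative. With the preset alone positive lists were immune receptors (4 of 25, blocked 9, FDR 2e-04, estimated 0.21), heat shock (1 of 20, blocked 10, FDR 0.0015, estimated 0.48), ER chaperones (0 of 12, unadjusted 3, DESeq2 1, blocked 9, FDR 0.005, estimated 0.36) and floral identity (2 of 22, blocked 10 higher and 1 lower, FDR 0.00088, estimated 0.1). Leaf photosynthesis was negative by it (0 of 28, unadjusted 2, DESeq2 1, blocked 10, FDR 0.0083, estimated 0.64). In all 628 genes passed, 576 positive and 52 negative. The count was 3887 (1399 lower) blocked, 181 (9 lower) in the compared groups alone and 718 (83 lower) with DESeq2. Leaving out 1 library gave 356 and 331 without WT 0 h R1 or R2, 329 and 295 without WT 12 h R1 or R2, 354 and 315 without zed1-D 0 h R1 or R2, 350 and 352 without zed1-D 12 h R1 or R2, 22 to 28 lower. ADR1-L2 (0.053, 1) failed without WT 12 h R2. SEP2 (0.087, 6) failed without zed1-D 0 h R2.

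At 48 h it was positive for PR2 (4.12 ± 0.19, FDR 4.6e-06), KTI1 (5.69 ± 0.36, FDR 1.9e-05), NIT2 (3.9 ± 0.29, FDR 7.3e-05), RLP38 (2.91 ± 0.19, FDR 2.2e-05), CRK4 (2.39 ± 0.18, FDR 7.7e-05) and PR1 (2.47 ± 0.54, FDR 0.031). It was negative for the anthocyanin genes DFR (-3.89 ± 0.21, FDR 1.1e-05) and GSTF12 (-3.33 ± 0.21, FDR 1.9e-05) and for ORG1 (-2.33 ± 0.18, FDR 7.7e-05), and AT5G37940 also passed with fewer counts in zed1-D (FDR 1.1e-05). Salicylic-acid defence (12 of 22, blocked 20 higher and 1 lower, median 2.08, FDR 6.6e-40, estimated 0.00076), pattern-triggered and camalexin (7 of 18, blocked 12 higher and 1 lower, median 1.12, FDR 1.6e-09, estimated 0.00089) and senescence (4 of 11, blocked 7, median 1.97, FDR 2e-10, estimated 0.00089) were positive. Cold response (2 of 7, blocked 5, median -1.32, FDR 3.2e-06, estimated 0.0063), cell cycle (1 of 22, blocked 14, median -0.51, FDR 4.6e-06, estimated 0.005) and glucosinolate (5 of 13, blocked 1 higher and 9 lower, median -0.59, FDR 2.1e-06, estimated 0.017) were negative. By the preset alone immune receptors (3 of 25, blocked 11, FDR 0.00061, estimated 0.23) and ER chaperones (2 of 12, blocked 9, FDR 5.1e-05, estimated 0.21, blocked estimated 0.036) were positive. Negative by it were jasmonate (1 higher and 2 lower of 18, blocked 1 higher and 10 lower, FDR 0.008, estimated 0.48, blocked estimated 0.0059) and tapetum (0 of 10, unadjusted 2, DESeq2 0, blocked 3, FDR 0.015, estimated 0.13, blocked 0.06). In all 713 genes passed, 486 positive and 227 negative. The count was 5258 (2710 lower) blocked, 258 (59 lower) in the compared groups alone and 512 (147 lower) thinned. With 1 library left out it was 411 and 386 without WT 0 h R1 or R2, 437 and 382 without WT 48 h R1 or R2, 435 and 382 without zed1-D 0 h R1 or R2, 478 and 458 without zed1-D 48 h R1 or R2, 108 to 155 lower. PR1 (0.12, 5) failed without WT 0 h R2.

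Across all genes the changes since 0 h in zed1-D and WT correlated at r = 0.197 at 3 h, 0.376 at 12 h and 0.403 at 48 h. Genes are not independent replicates, and the genotypes' changes rest on separate libraries. Of genes that passed in WT, 256 of 343 (74.6%) at 3 h, 260 of 292 (89.0%) at 12 h and 477 of 574 (83.1%) at 48 h had the same sign in zed1-D.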

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

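The test on evening clock genes and the test on floral organ identity genes were chosen after the results were seen. The depth test rests on thinning, which was also chosen after the split was seen, though before the thinned value was. The length test was chosen before its result was seen.

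Each interaction value here drew attention because the zed1-D effect differed between 0 h and a later time by an interaction test. Interactions passed for 205 genes at 3 h, 628 at 12 h and 713 at 48 h. At 3 h the list medians were 2 for salicylic-acid defence, 1.47 for pattern-triggered and camalexin, 1.62 for senescence, 0.97 for tapetum, 1.47 for pollen and -0.43 for glucosinolate. At 12 h they were 1.68 for salicylic-acid defence, 1.5 for pattern-triggered and camalexin, 1.28 for jasmonate, 1.09 for senescence, 2.62 for pollen, -0.34 for cell cycle and -1.05 for glucosinolate. At 48 h they were 2.08 for salicylic-acid defence, 1.12 for pattern-triggered and camalexin, 1.97 for senescence, -1.32 for cold response, -0.51 for cell cycle and -0.59 for glucosinolate. The PR1 interaction was 3.05 at 3 h and 2.47 at 48 h. Interactions also carry the 0 h difference, with medians of -0.56 for tapetum, -0.68 for pollen and 0.15 for cell cycle. The 12 h genotype difference itself was 1.73 for pollen (estimated 0.031, blocked estimated 0.1), and for cell cycle it did not pass (-0.17, adjusted p = 0.06).

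The libraries split by replicate number in every group, on the second principal component. Unequal depth between the replicate sets is argued against, since the median correlation of same-numbered deviations was 0.61 after thinning all libraries to equal depth and 0.65 before. Gene length and GC content accounted for 13.5% of the variance of the mean set difference across 18945 genes (98.1% of those tested), which argues against them as the main source. A different day, growth batch or library batch may lie behind the split, and the labels give none of these. No biological explanation was tested.

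Morning clock genes were higher in zed1-D at 48 h (median 1.74 over 4 genes). A different sampling time for zed1-D and WT could give this, and evening genes might then move the other way. Their median was -0.16 over 7 genes, within 2 standard errors (0.22) of 0. Of these 4 were negative and 1, BOA, passed (FDR 0.026). In WT by 3 h LHY and LUX rose and ELF4 fell, so the set cannot decide. In the whole clock list 4 of 14 genes passed as higher and 3 as lower, including FKF1, not in the evening set. Sampling time and a genotype effect on the clock cannot be told apart, since the labels give no clock time.

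Tapetum markers were lower in zed1-D at 48 h, in 2 libraries per group (median -1.29, estimated 0.031, blocked estimated 0.15). Their list was already down at 0 h (median -0.56, estimated 0.0088), and the 48 h interaction did not pass as estimated (0.13). A smaller share of flowers as the main source is argued against. For 6 floral organ identity genes the median was -0.08 (standard error of members 0.15) where -0.64 or below was needed. The floral list (median -0.35, 3 lower, 0 higher) leaves a smaller loss open. Floral stage or a genotype effect on anthers may explain the tapetum shift. Neither was tested.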

How the results depend on the processing

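Thinning to equal depth was chosen after the results were seen, and the other settings before. For the changes named here the cause was not tested, except that fits with fewer libraries hold fewer degrees of freedom. The alternative pseudocount was planned for normalised values and was not run for counts.

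In contrast order (zed1-D against WT at 0, 3, 12 and 48 h, WT at 3, 12 and 48 h against 0 h, zed1-D likewise, then interactions at 3, 12 and 48 h), the replicate block gave 438, 3304, 6783, 8807, 3912, 4107, 5675, 4608, 8485, 10187, 1093, 3887 and 5258 genes. A fit of the compared groups alone gave 0, 145, 732, 1322, 0, 0, 5, 0, 1111, 2203, 29, 181 and 258, with 239, 1077, 1136 and 1771 genes at an unadjusted p under 0.05 in edgeR where it gave 0, and 34, 548, 480 and 671 by DESeq2 on all libraries. DESeq2 moved the count by over 1.5 times at 0 h (34) and for WT at 3 h (548) and 12 h (480). The fold minimum did so for zed1-D against WT at 48 h (1642), WT at 3, 12 and 48 h (210, 159 and 310) and zed1-D at 3, 12 and 48 h (325, 1687 and 2281). RLE scaling, no filter and thinning kept every total within 1.5 times, but not every lower count, as at 3 h (45, 23 with no filter and 27 thinned). Such lower counts are given with each result.

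With 1 library left out, in the same order, counts ran from 0 to 3, 309 to 398, 939 to 1278, 1417 to 1796, 110 to 120, 54 to 65, 95 to 168, 122 to 204, 1565 to 1884, 1948 to 2812, 101 to 133, 295 to 356 and 382 to 478. The 0 h counts of 0, without WT 0 h replicate 1 or 2, had 526 and 617 genes at an unadjusted p under 0.05 in edgeR. The remaining library of that group was assumed to vary like the other groups.

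Of 289 gene and comparison pairs allowed by the naming rule, 270 passed, and 282 with the block, 269 with RLE, 270 with DESeq2, 255 with no filter, 249 thinned and 139 in the compared groups alone. With 1 library of the compared groups left out, ZED1 ran from -1.12 to 0.55 at 0 h, -0.92 to 0.96 at 3 h, -0.34 to 0.95 at 12 h and -1.09 to 0.36 at 48 h. ZAR1 at 0 h ran from -0.16 to 0.07, SNC1 at 0 h from -0.07 to 0.09, PR1 in zed1-D at 3 h from -0.10 to 0.58 and the PR1 interaction at 12 h from -0.06 to 0.68. None of these passed in any omission. ZED1 at 0 h also changed sign with the block (0.03), RLE (0.01) and no filter (0.02), and thinned ZED1 did at 3 h (0.14) and 48 h (0.06), all without a call.

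Of 234 list tests, 146 passed with the preset correlation, 84 with the estimated correlation and 143 with the block. Directions reversed with the block only where neither passed: senescence at 0 h (adjusted p = 0.92) and in WT at 12 h (0.97), jasmonate at 3 h (0.79), reference genes at 3 h (0.74), 12 h (0.80) and in the interactions at 3 h (0.60) and 12 h (0.63), ZED1-related kinases in zed1-D at 48 h (0.94) and heat shock in the 48 h interaction (0.89). Outside the genotype contrasts the block gained endoplasmic reticulum (0.030) and leaf lists (1.9e-09) in WT at 12 h and jasmonate (0.044) and cold response (0.0017) in the 3 h interaction. Beside these and the values given with each result, the block changed no other call with the preset correlation. With the estimated correlation 84 tests passed without the block and 87 with it, 14 being lost and 17 gained. The cold-response list in the 3 h interaction (0.032) was among those gained, and the others are given with each result.

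For lack of reads 22 of the 302 list genes were not tested, and thinning to equal depth left 249 of the 270 named pairs passing. In data simulated under the blocked model, the unblocked calls recovered 22.4% of log2 changes of 1 and the blocked calls 97.0%.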

Other observations

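The anthocyanin and iron-deficiency lists and tests were chosen after the results were seen. They hold 12 and 13 genes, and p-values are adjusted over their 26 tests. Each list holds 4 genes whose values prompted it, DFR, GSTF12, AT5MAT and TT8 in the first and AT2G30766, BHLH100, ORG1 and NAS4 in the second, so the full-list tests partly repeat that observation. Tests without these genes, adjusted alike, follow for the main results.

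Anthocyanin and flavonoid genes were lower in zed1-D at 48 h, with 8 of 12 passing (11 blocked) and a median of -2.75 (adjusted p = 2.1e-22, estimated 3.2e-05). Without the prompting genes 4 of 8 passed (7 blocked), with a median of -1.54 (estimated 0.0024), and the 48 h interaction had a median of -1.38 (estimated 0.0024). DFR stood at 4.88 ± 0.886 against 64.5 ± 4.54 CPM, LDOX at 4.96 ± 1.38 against 68.5 ± 10.7, UF3GT at 1.98 ± 0.421 against 27.8 ± 3.10 and GSTF12 at 3.06 ± 0.304 against 32.8 ± 3.93. CHS, the entry enzyme of the pathway, did not pass (431 ± 136 against 661 ± 271 CPM, adjusted p = 0.53, blocked 1.5e-07). In WT at 48 h against 0 h edgeR called 0 of the genes (2 higher and 3 lower blocked, median -0.13, adjusted p = 0.63), while zed1-D had 7 lower (median -3.01, estimated 4.2e-05). The interaction at 48 h had a median of -2.59 with 6 genes lower and 10 blocked (estimated 1.3e-05). At 12 h 2 were lower in zed1-D than in WT and 4 blocked (median -0.41, estimated 0.036), a list call lost without the prompting genes (estimated 0.13).

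Iron-deficiency genes rose with time in WT. Medians were 1.5 at 3 h (5 of 13 higher, 8 blocked), 2.85 at 12 h (11 higher) and 4.49 at 48 h (12 higher). Each estimated p was at most 4e-05. Without the prompting genes the medians were 1.21, 2.85 and 4.57 (estimated 0.0024, 2.4e-05 and 1.8e-05). In zed1-D 10 were higher and 1 lower at 48 h (median 1.78, estimated 0.00054). At 0 h the list was higher in zed1-D (2 higher, 8 blocked, median 1.33, estimated 1.2e-05). At 48 h it was lower (4 lower, 10 blocked, median -0.86, estimated 0.0048). The other 9 kept both shifts (medians 1.33 and -0.63, estimated 0.0005 and 0.03). None passed at 0 h (5 blocked), where BHLH38, BHLH39 and BHLH101 had at most 0.322 CPM. The full list was higher at 3 h (median 0.92, estimated 0.0038) and did not pass at 12 h (median -0.18, FDR 0.13). The interaction was negative at 3 h (median -0.5, estimated 0.0038, and 0.13 without the prompting genes), 12 h (median -1.5, estimated 0.00016) and 48 h (median -2.11, estimated 1e-04), and carries the 0 h difference.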
